A study of Arabidopsis thaliana with 9 samples.

How the data were processed

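Small RNA libraries of 2-week-old seedlings were made from Col-0, cyp71-2 and cyp71-3, 3 per genotype, and 9 in all. Per the labels' protocols, total RNA was enriched for small RNA by precipitation, a small RNA fraction was excised from a denaturing gel, and libraries were made with a ligation-based small RNA kit and sequenced on an Illumina instrument. Per the submitters' processing notes, cutadapt 3.1, Bowtie 1.3.0 and the build TAIR10 were used, with parameters not given in the sources used here. The deposited files give, for each library, distinct sequences of 16 to 26 nt with their level in RPM, per the file headers. The scaling was to all reads of the library, since the RPM of each library summed to between 999628 and 1000462.

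The smallest step between RPM values gave the worth of 1 read in each library, and 100% of values were whole reads within 0.1 read (largest offset 0.0283 reads). The recovered depths were between 5538323 and 16768022 reads. Counting error alone gave a coefficient of variation of 7.72% to 13.4% at 10 RPM, and a count of 0 allowed up to 0.179 to 0.542 RPM (3 reads). These limits cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules. Replicate libraries differed by more than sampling noise (chi-square per degree of freedom 4.39 to 34.5), so none was taken for a second copy of another. This does not tell separate cultures from repeat preparations.

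Sequences were matched exactly to TAIR10.1, and at least 99.9988% of the distinct sequences of each library matched. A mature miRNA was counted by its exact annotated sequence. Sequences shared by loci of a family were counted as 1 item. The annotation marks neither arm as the main strand, so the arm of each fixed name was chosen by convention. Reads of other loci were assigned to classes by their genome position. siRNAs of loci annotated as pseudogenes were counted from reads of 21 to 24 nt with a single genome match. This class may hold transposons, and it was not divided into transposons and other pseudogenes.

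Levels of miRNAs were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend and robust) on log2(RPM + 1), with all 9 libraries in a single fit so that genotypes share an estimate of the spread, without a block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. miRNAs with at least 1 RPM in at least 3 libraries were tested. Single values per library were compared by exact permutation tests over the 20 arrangements of 6 libraries. Lists of families were tested with camera (preset correlation 0.01, and an estimated one) and fry. TAS loci were tested in a limma fit with MIRNA precursors. The agreement of the mutants, for miRNAs and for pseudogene siRNAs, was set beside 100 simulations of unchanged groups against the same controls. On simulated data for 126 miRNAs with 40 changed, in 20 runs of the comparison of cyp71-2 with Col-0, limma recovered 97% of 3-fold and 88.5% of 2-fold changes, and 4.01% of its calls were false. On the same data edgeR recovered 97% and 86.5%, and DESeq2 95% and 80.75%. These data had as many rises as falls, a dispersion of 0.02 and independent miRNAs. That dispersion was a set value, not estimated from these libraries. Many miRNAs varied more between Col-0 replicates, so recovery may be overstated for them. For limma they were scaled by the totals they were drawn with, so the false share does not cover errors of scaling.

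The tests, comparisons, lists, naming rule and most alternatives were fixed before the data were examined. By the naming rule, the text names, per mutant, the 10 miRNAs that fell most and the 10 that rose most among those with an adjusted p under 0.05, a mean of at least 10 RPM in Col-0 or the mutant, and all 3 mutant libraries on the same side of all 3 Col-0 libraries. It also names the 10 most abundant miRNAs in Col-0, 25 fixed names whether or not they passed, and 6 TAS loci. Where fewer than 10 met the rule, all of them are named. The 9 lists were conserved families, Brassicaceae-restricted families, nutrient-responsive families, RNA silencing regulators, triggers of trans-acting siRNAs, loop-to-base processed families, DCL4-processed families, auxin and leaf development families, and phase change and flowering families.

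Alternatives were other pseudocounts (0.1 and 10 RPM), no filter, a mean of at least 10 RPM, median-of-ratios size factors, scaling to the 24-nt reads, a replicate block, only the 6 libraries of a pair, edgeR 4.0.16 (quasi-likelihood with TMM) and DESeq2 1.42.0 on the recovered reads, isomiRs overlapping the mature miRNA by at least 16 nt, and leaving out each library. Chosen after seeing the data were scaling to reads of 17 to 26 nt, scaling to reads outside rRNA, tRNA, snRNA and snoRNA, the other scalings of summed TAS reads, the replicate block for TAS loci, and all alternatives for the agreement of the 2 mutants. Reads were matched with numpy 2.4.6, pandas 2.3.3 and numba 0.67.0, exact tests used scipy 1.17.1 and figures matplotlib 3.10.9, in Python 3.11.15. mRNA libraries of the same study were not analysed here.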

Results

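Small RNAs were sequenced from 2-week-old Arabidopsis thaliana seedlings of the wild type Col-0 and of the mutants cyp71-2 and cyp71-3, with 3 libraries per genotype. CYP71 (AT3G44600, chromosome 3, 16164935 to 16169304, TAIR10.1) encodes a cyclophilin, a class of enzymes that isomerise peptide bonds before proline. The series asks how mutations of this gene affect miRNA processing, in which the zinc-finger protein SERRATE assists the nuclease DCL1. Each library listed distinct sequences of 16 to 26 nt with their level in RPM (reads scaled to the library total). The Col-0 libraries held 16768022, 15636052 and 12556586 reads. The cyp71-2 libraries held 11116450, 5538323 and 9973869 reads, and the cyp71-3 libraries held 11883516, 16090851 and 14338102. A value of 1 RPM rested on between 5.54 and 16.8 reads. Reads on the sense strand of CYP71 numbered 13, 13 and 4 in Col-0, 12, 6 and 21 in cyp71-2, and 2, 3 and 2 in cyp71-3. These fragments do not measure the mRNA and check no label. Nothing in the labels says that the libraries of a genotype came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of 350 annotated mature miRNA sequences, 271 were detected and 126 were tested. A mature sequence shared by several loci is reported as 1 item, since its reads cannot be divided among the loci.

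In cyp71-2, miRNAs were lower than in Col-0 more often than they were higher, and a few rose strongly. Among miRNAs with a mean of at least 10 RPM in Col-0 or the mutant, the largest fall on the log2(RPM + 1) scale was that of miR3932b-5p, from 37.7 ± 3.67 RPM (SD, n = 3) in Col-0 to 4.69 ± 0.997 RPM (SD, n = 3). The largest rise was that of miR845a, a miRNA that pairs with the primer-binding site of retrotransposons, from 21.5 ± 4.50 to 253 ± 30.2 RPM (SD, n = 3), an 11.8-fold ratio of means. The abundant miR159a and miR159b-3p, which repress GAMYB-like transcription factors, fell from 1344 ± 197 to 849 ± 182 RPM and from 1013 ± 83.3 to 442 ± 102 RPM (SD, n = 3). The copper-responsive miR398b/c-3p, which targets copper superoxide dismutase transcripts, rose from 943 ± 81.2 to 1981 ± 174 RPM (SD, n = 3).

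With limma and Benjamini-Hochberg adjustment, 51 miRNAs were lower and 17 higher in cyp71-2 at an adjusted p under 0.05. The count at an unadjusted p under 0.05 was 70. The median log2 change of the 126 miRNAs was -0.30 as deposited and 0.02 with median-of-ratios size factors, under which 36 miRNAs were lower and 33 higher. Falls and rises are therefore relative to all reads of the library, and fold changes are on the log2(RPM + 1) scale, which understates the change of scarce miRNAs. Median-of-ratios size factors are computed from the tested miRNAs, which centres their median change by construction. DESeq2 uses such factors and edgeR a related scaling (TMM) on the same miRNAs, so these methods are not independent of one another.

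Among the miRNAs that fell, miR3932b-5p (TTTGACGTGCTCGATCTGCTC, chromosome 4, 7890695 to 7890715, TAIR10.1) changed by a log2 of -2.78 with a standard error of 0.23 (limma, Benjamini-Hochberg adjusted p = 1.89e-15). miR169f-3p fell by 1.89 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 2.02e-09) and lay in MIR169f on chromosome 3, 4805713 to 4805733. miR846-3p dropped from 63.2 ± 12.2 to 17.4 ± 4.54 RPM (SD, n = 3). miR395b/c/f, which targets sulfate assimilation genes, went from 13.4 ± 2.39 to 3.40 ± 0.807 RPM (SD, n = 3). miR858a and miR858b, which target MYB transcription factors, fell by 1.28 and 1.24 on the log2 scale. miR159b-3p (TTTGGATTGAAGGGAGCTCTT, chromosome 1, 6220813 to 6220833) fell by 1.22, and miR167c-3p by 1.23. miR158a-5p fell by 1.05 while its partner strand miR158a-3p, at 1725 ± 375 RPM in Col-0 and 1420 ± 354 RPM in cyp71-2 (SD, n = 3), did not pass the test and turned direction with median-of-ratios size factors. miR447a.2-3p fell by 0.99, and miR822-5p and miR399b,miR399c-3p by 0.55 and 0.59.

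Among the miRNAs that rose, miR845a (CGGCTCTGATACCAATTGATG, chromosome 4, 12217457 to 12217477, TAIR10.1) changed by a log2 of 3.51 with a standard error of 0.22 (limma, Benjamini-Hochberg adjusted p = 2.53e-20). miR843 (chromosome 3, 17742147 to 17742167) rose from 5.09 ± 0.909 to 52.7 ± 11.3 RPM (SD, n = 3). The copper-responsive miR398b/c-5p, miR398a-3p, miR408-5p and miR408-3p had log2 changes of 1.3, 1.23, 1.28 and 0.96. miR393b-3p, the partner strand of a regulator of auxin receptors, rose from 248 ± 33.7 to 519 ± 128 RPM (SD, n = 3). miR156, the miRNA of the juvenile phase made from 6 loci, rose from 301 ± 79.7 to 540 ± 110 RPM (SD, n = 3), and miR158b rose by a log2 of 0.72. By the rule for naming by size, which includes that all 3 mutant libraries lie on the same side of all 3 Col-0 libraries, 27 miRNAs qualified as lower and 11 as higher. Chance alone separates 3 libraries from 3 for 10% of any miRNAs, before the conditions on adjusted p and level, so it is not the count expected under this rule.

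The most abundant miRNA, miR161.1 (TGAAAGTGACTACATCGGGGT, chromosome 1, 17825731 to 17825751), a Brassicaceae miRNA that targets pentatricopeptide repeat genes, made up 50.6 ± 2.28% of mature miRNA reads in Col-0 (SD, n = 3). Its level was 11192 ± 1211 RPM in Col-0 and 10177 ± 1031 RPM in cyp71-2 (SD, n = 3), which did not pass the test. With median-of-ratios size factors its direction turned and it passed as higher (limma, Benjamini-Hochberg adjusted p = 0.0326). edgeR and DESeq2, which also scale on the miRNAs, called it higher too. miR162a/b-3p, which targets DCL1, fell from 708 ± 23 to 404 ± 51.0 RPM (SD, n = 3). miR403-3p, which targets AGO2, fell by 0.91 on the log2 scale, and miR163 by 0.82. miR168a/b-5p, which targets AGO1, stood at 14.8 ± 2.41 and 14.0 ± 2.75 RPM (SD, n = 3), did not pass and turned direction with median-of-ratios size factors. Among leaf and meristem regulators, miR165 fell from 220 ± 29.2 to 125 ± 21 RPM (SD, n = 3), while miR166, made from 7 loci, was at 601 ± 94.1 and 569 ± 112 RPM (SD, n = 3) and did not pass. With median-of-ratios size factors miR166 had the opposite direction and passed as higher (limma, Benjamini-Hochberg adjusted p = 0.0262), as it did with edgeR and DESeq2. miR396b-5p, miR396a-5p, miR172 (miR172a,miR172b-3p), miR5026, miR160, miR167 and miR173-5p fell by 0.89, 0.88, 0.71, 0.62, 0.64, 0.58 and 0.64 on the log2 scale, and miR164 rose by a log2 of 0.51. Of the named falls in cyp71-2, those of miR160, miR167, miR173-5p, miR396a-5p, miR399b,miR399c-3p, miR822-5p and miR5026 no longer passed with median-of-ratios size factors, nor that of miR172 with edgeR and DESeq2 or that of miR159a with edgeR. The rise of miR164 (limma, Benjamini-Hochberg adjusted p = 0.0470) was lost without any 1 of the 9 libraries, and leaving out some 1 library also ended the calls of miR158b, miR160, miR167, miR173-5p, miR399b,miR399c-3p and miR822-5p. miR157, miR171a-3p, miR319a/b, miR390, miR393a/b-5p and miR827 did not pass, with log2 changes of 0.37, -0.42, 0.21, 0.40, 0.13 and -0.20, and miR827 turned direction with median-of-ratios size factors, as miR319a/b and miR393a/b-5p did when scaled to reads outside rRNA, tRNA, snRNA and snoRNA.

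Of the 9 lists of families fixed beforehand, only the nutrient-responsive list was called by camera in cyp71-2, upward (limma camera, Benjamini-Hochberg adjusted p = 0.0120). That call was lost with an estimated correlation (adjusted p = 0.865 with an estimated correlation, limma camera). Of its 12 members, 7 were higher and 3 lower over all miRNAs tested, and 7 higher and 3 lower when adjusted over the list alone. The members that rose were of the copper-responsive families, and miR395b/c/f and miR399b,miR399c-3p, which respond to sulfate and phosphate shortage, fell. Conserved families had 24 members lower and 13 higher of 67, and 24 and 13 adjusted over the list alone. Brassicaceae-restricted families had 15 lower and 3 higher of 32, and 15 and 3 adjusted over the list alone. Regulators of RNA silencing had 4 of 7 lower, and 4 adjusted over the list alone. In every list both arms of a hairpin count as separate members, and here miR168a/b-5p was not among those lower. The loop-to-base processed families miR159 and miR319 had 4 of 6 lower, the DCL4-processed families 2 of 2, and the triggers of trans-acting siRNAs 1 of 3, with the same counts adjusted over the list alone. All 4 of the lower loop-to-base members were of miR159, and neither miR319a/b nor miR319c passed. Auxin and leaf development families had 7 lower and 3 higher of 25 (6 and 2 adjusted over the list alone), and phase change and flowering families 6 lower and 3 higher of 18 (6 and 3 adjusted over the list alone). The fry test of limma, which asks whether members move on balance one way, called 3 lists downward, namely DCL4-processed, loop-to-base processed and RNA silencing regulators (Benjamini-Hochberg adjusted p = 0.0131, 0.0255 and 0.0297). It was run on the deposited scaling only, where the median change of all miRNAs was below 0. It therefore does not tell these falls from that shift. For the conserved, auxin, phase change and trigger lists, camera pointed up, relative to other miRNAs, while medians and means were below 0.

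**Figure D1:**
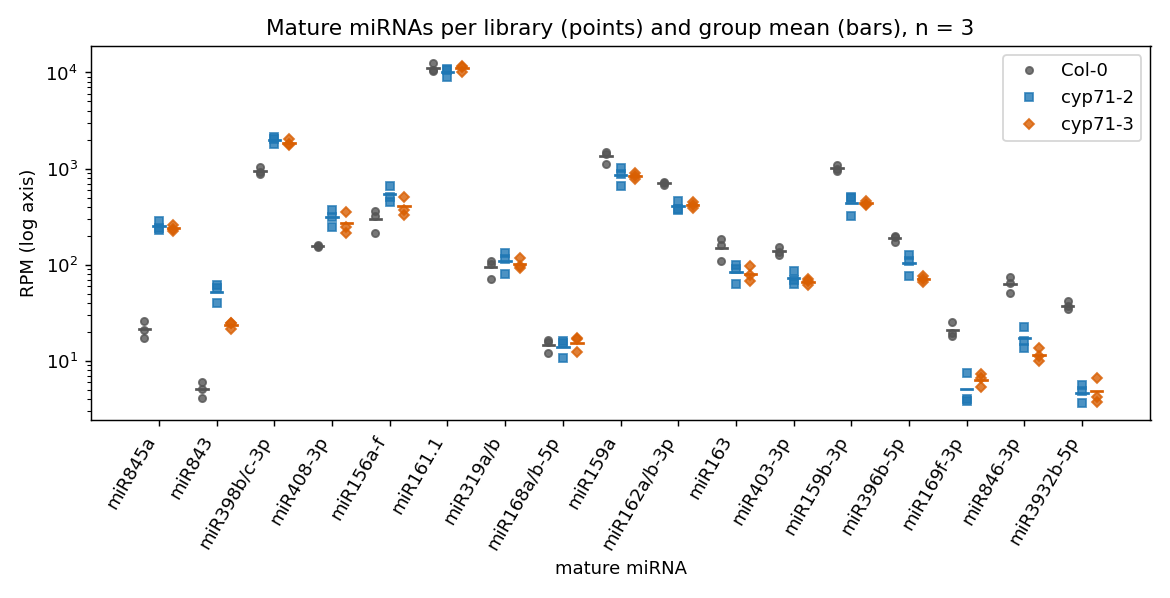
Level of 17 named miRNAs in each library, in RPM on a log axis, for Col-0, cyp71-2 and cyp71-3. Points are libraries and short bars are means of 3 libraries. miR845a and miR843 lie higher in both mutants and miR3932b-5p, miR846-3p and miR159b-3p lower. miR161.1 overlaps, and with median-of-ratios size factors it turns direction and passes as higher in both mutants.

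In cyp71-3 the same lead miRNAs stood out. miR845a rose to 240 ± 16.0 RPM (SD, n = 3), an 11.2-fold ratio of means to Col-0, and miR843 to 23.6 ± 1.79 RPM (SD, n = 3). miR3932b-5p fell to 4.85 ± 1.56 RPM (SD, n = 3) and miR846-3p to 11.6 ± 1.79 RPM (SD, n = 3). miR159b-3p and miR159a fell to 437 ± 24.8 and 836 ± 64.6 RPM (SD, n = 3), and miR398b/c-3p rose to 1861 ± 167 RPM (SD, n = 3).

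With limma and Benjamini-Hochberg adjustment, 49 miRNAs were lower and 10 higher in cyp71-3 at an adjusted p under 0.05, and 67 passed at an unadjusted p under 0.05. The median log2 change was -0.38 as deposited and -0.02 with median-of-ratios size factors, under which 33 miRNAs were lower and 30 higher.

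Among miRNAs with a mean of at least 10 RPM in Col-0 or the mutant, the largest falls in cyp71-3 on the log2(RPM + 1) scale were those of miR3932b-5p, by 2.75 on the log2 scale with a standard error of 0.23 (limma, Benjamini-Hochberg adjusted p = 4.03e-15), and of miR846-3p, by 2.34 (limma, Benjamini-Hochberg adjusted p = 9.77e-13). miR169f-3p fell by 1.57, miR396b-5p by 1.41, miR447a.2-3p by 1.37, miR399b,miR399c-3p by 1.33, miR822-5p by 1.27, miR159b-3p by 1.21, miR396a-5p by 1.20 and miR403-5p by 1.19 on the log2 scale. The miR396 family represses growth-regulating factors, and miR822 is a young miRNA made by DCL4. Above the same level, the rises were those of miR845a, by a log2 of 3.44 (limma, Benjamini-Hochberg adjusted p = 6.35e-20), miR843 by 2.02, miR408-5p by 1.0, miR398b/c-3p by 0.98, miR398b/c-5p by 0.86, miR158b by 0.77, miR408-3p by 0.76 and miR398a-3p by 0.75. The other called rises were those of the scarcer miR397b, by a log2 of 1.04, and miR8183, by 0.75, both named after their values were seen. By the rule for naming by size, 26 miRNAs qualified as lower and 8 as higher, where chance alone separates the groups for 10% of any miRNAs, before the conditions on adjusted p and level.

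miR162a/b-3p fell to 420 ± 30.6 RPM, miR403-3p to 66.9 ± 4.50 RPM, miR163 to 80.6 ± 14.2 RPM and miR165 to 135 ± 13 RPM in cyp71-3 (SD, n = 3). miR160 and miR167 fell by 0.70 and 0.54 on the log2 scale, miR5026 by 0.50, with a direction that turned under edgeR. With median-of-ratios size factors, miR158a-5p, miR159a, miR160, miR162a/b-3p, miR165, miR167, miR5026 and miR858b no longer passed in cyp71-3. The calls of miR158a-5p, miR160, miR167, miR398a-3p and miR5026 were also lost on leaving out some 1 library. With median-of-ratios size factors miR161.1, miR157, miR171a-3p and miR393b-3p passed as higher (limma, Benjamini-Hochberg adjusted p = 0.000624, 0.0259, 0.0335 and 0.0317). They passed as higher with edgeR and DESeq2 too. As deposited, where their direction was the opposite, miR161.1 (11091 ± 827 RPM, SD, n = 3), miR157 (49.3 ± 9.49 RPM), miR171a-3p (18.4 ± 1.57 RPM) and miR393b-3p (229 ± 21.1 RPM) did not pass. miR156, miR158a-3p, miR164, miR166, miR168a/b-5p, miR172 (miR172a,miR172b-3p), miR173-5p, miR319a/b, miR390, miR393a/b-5p and miR827 did not pass either, with log2 changes of 0.44, -0.25, 0.38, -0.35, 0.06, -0.35, -0.46, 0.13, 0.25, 0.30 and -0.53. The direction turned for miR158a-3p, miR166, miR172 and miR173-5p with median-of-ratios size factors, for miR168a/b-5p and miR319a/b when scaled to 24-nt reads, and for these 2 and miR390 when scaled to reads outside rRNA, tRNA, snRNA and snoRNA. The scarcer miR172c,miR172d-3p, named after its values were seen, did fall in cyp71-3, from 5.28 ± 1.73 to 1.06 ± 0.481 RPM (SD, n = 3). Its log2 change was -1.60 there (limma, Benjamini-Hochberg adjusted p = 3.78e-07) and -1.41 in cyp71-2.

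Camera again called only the nutrient-responsive list in cyp71-3, upward (limma camera, Benjamini-Hochberg adjusted p = 0.0102), with 6 of 12 members higher and 2 lower, and 6 and 2 adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.624 with an estimated correlation, limma camera). Conserved families had 20 members lower and 6 higher of 67 (19 and 6 adjusted over the list alone), and Brassicaceae-restricted families 17 lower and 3 higher of 32 (18 and 3 adjusted over the list alone). RNA silencing regulators had 4 of 7 lower, loop-to-base processed families 4 of 6 and DCL4-processed families 2 of 2, with the same counts adjusted over the list alone. The lower loop-to-base members were miR159a, miR159b-3p, miR159c and miR319c. Auxin and leaf development families had 7 of 25 lower (5 adjusted over the list alone), phase change and flowering families 5 of 18 (5 adjusted over the list alone), and no trigger of trans-acting siRNAs passed either way. The fry test of limma called 4 lists downward, the 3 called in cyp71-2 and the Brassicaceae-restricted list (Benjamini-Hochberg adjusted p = 0.0433). As in cyp71-2, it was run on the deposited scaling only, so these falls are not told from the shift of all miRNAs. Camera pointed up for the conserved, auxin, phase change and trigger lists, while their medians and means were below 0.

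Between the 2 mutants, 11 miRNAs differed, 9 of them lower and 2 higher in cyp71-3 (limma, Benjamini-Hochberg), and 20 passed at an unadjusted p under 0.05. miR393b-3p was lower in cyp71-3 than in cyp71-2, with a log2 difference of -1.15 (limma, Benjamini-Hochberg adjusted p = 6.48e-05). miR843, raised in both mutants, was lower in cyp71-3 by a log2 difference of -1.11 (limma, Benjamini-Hochberg adjusted p = 0.000257). miR399b,miR399c-3p and miR822-5p were lower in cyp71-3, and miR395b/c/f was higher. The scarcer miR391-3p, miR393a-3p, miR398a-5p, miR472-5p and miR866-3p were lower and miR8183 higher in cyp71-3, and these 6 names were chosen after their values were seen. The count was 21 with median-of-ratios size factors, and 7 without Col-0 replicate 2, without cyp71-3 replicate 2 or without cyp71-3 replicate 3.

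The changes of the 2 mutants were alike across miRNAs: 43 miRNAs, miR3932b-5p and miR159b-3p among them, were lower in both, 9 were higher in both, and 0 were called in opposite directions. Pearson's r across the 126 miRNAs was 0.905 and Spearman's rho was 0.876, where miRNAs are not independent replicates. Both comparisons used the same Col-0 libraries, and simulated unchanged groups against those controls gave an r of 0.488, a rho of 0.474 and 0 shared calls. Independent lists of these sizes would share 19.8 lower and 1.35 higher miRNAs. The covariance of the log2 changes was 0.619, against 0.0245 in the simulations, a difference of 0.594. The same direction was seen for 87.3% of miRNAs, against 66.8% simulated. The 3 controls cannot be split, so part of the excess over the simulations may come from the shared controls.

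**Figure D2:**
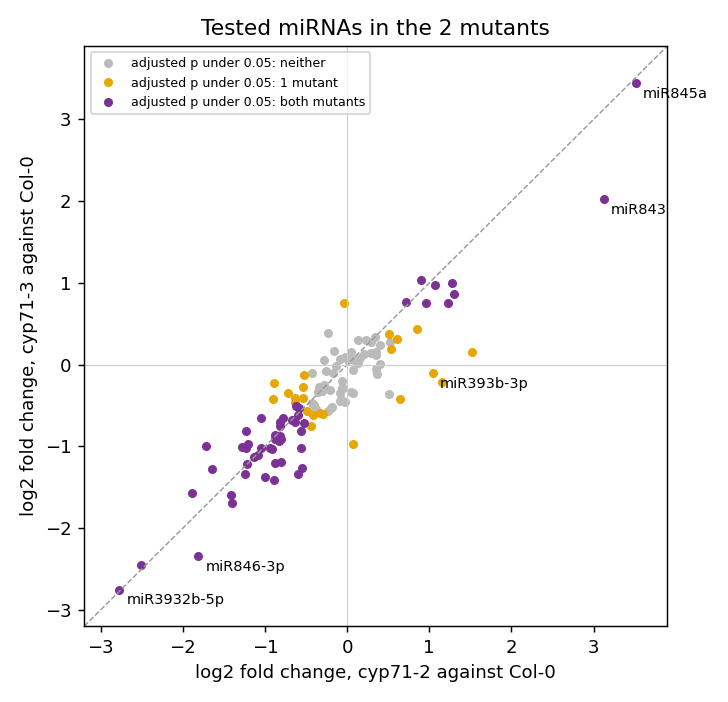
Log2 fold change on the log2(RPM + 1) scale of each of 126 tested miRNAs in cyp71-2 (horizontal axis) and cyp71-3 (vertical axis) against the same 3 Col-0 libraries. Points are coloured by the number of mutants with an adjusted p under 0.05, the dashed line marks equal change, and Pearson's r is 0.905. miR393b-3p lies off the line, and in cyp71-3 with median-of-ratios size factors it turns direction and passes as higher.

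Summed over all mature miRNAs, the level was 22133 ± 2236 RPM in Col-0, 20425 ± 2746 RPM in cyp71-2 and 20446 ± 1527 RPM in cyp71-3 (SD, n = 3). The differences were within the spread between libraries (two-sided exact permutation test, p = 0.5 for cyp71-2 and 0.4 for cyp71-3). With median-of-ratios size factors they turned upward, to a log2 of 0.28 and 0.37, with no overlap of either mutant with Col-0 (exact permutation p = 0.1 in each). With 3 libraries against 3, the smallest p of this test is 0.1, so no single value per library can pass 0.05.

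The 21-nt class, which holds most miRNAs and trans-acting siRNAs, made up 11.9 ± 0.184% of reads in Col-0, 10.2 ± 0.354% in cyp71-2 and 9.97 ± 0.194% in cyp71-3 (SD, n = 3). All 3 libraries of each mutant lay below all Col-0 libraries (two-sided exact permutation test, p = 0.1, the smallest possible). With each distinct sequence counted once the groups overlapped, and the difference was 0.12 percentage points in cyp71-2, in the opposite direction, and -0.05 in cyp71-3 (exact permutation p = 0.6 and 0.7). The 24-nt class, mostly siRNAs of heterochromatin, made up 18.6 ± 1.95%, 19.5 ± 0.700% and 21.4 ± 0.414% of reads (SD, n = 3). It overlapped Col-0 in cyp71-2 (exact permutation p = 0.6), where the difference turned without Col-0 replicate 3 (-0.21 percentage points) and without rRNA, tRNA, snRNA and snoRNA reads (-0.57), and lay above it in cyp71-3 (exact permutation p = 0.1). With each distinct sequence counted once, both mutants lay above Col-0, by 1.69 and 1.21 percentage points (exact permutation p = 0.1 in each). The 16-nt class took 6.61 ± 0.133%, 11.3 ± 0.517% and 9.27 ± 0.266% (SD, n = 3), with each mutant above Col-0 (exact permutation p = 0.1). In the same libraries 45S rRNA fragments took 48.4 ± 2.99%, 41.8 ± 2.53% and 40.7 ± 0.898% of reads (SD, n = 3).

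**Figure D3:**
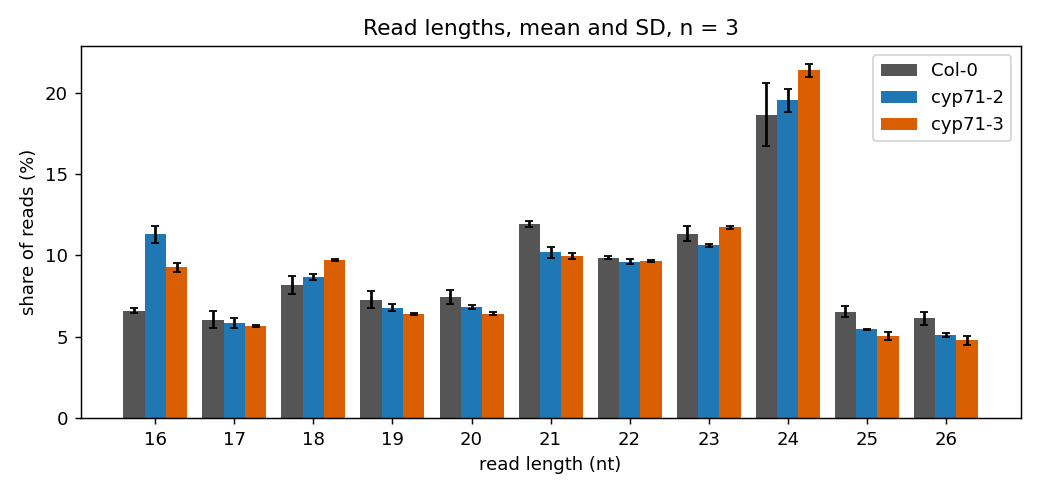
Share of reads, in percent, at each read length from 16 to 26 nt for Col-0, cyp71-2 and cyp71-3. Bars are means and whiskers SDs of 3 libraries; the 16-nt share is higher and the 21-nt share lower in both mutants.

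Processing precision was taken as the percent of a precursor's reads that start at an annotated mature 5′ end, with the median over 95 MIRNA precursors as the value of a library. It was 84.2 ± 0.615% in Col-0, 89.1 ± 0.325% in cyp71-2 and 89.8 ± 0.537% in cyp71-3 (SD, n = 3), with no overlap of either mutant with Col-0 (two-sided exact permutation test, p = 0.1). Counting reads that start within 1 nt of the annotated end, the medians were 96.6 ± 0.0337%, 97.1 ± 0.237% and 97.0 ± 0.478% (SD, n = 3), and cyp71-3 overlapped Col-0 (exact permutation p = 0.1 for cyp71-2 and 0.4 for cyp71-3). MIR156a, for example, went from 91.6 ± 1.34% to 96.1 ± 0.240% and 95.8 ± 0.302% (SD, n = 3), and was chosen as an example after its values were seen. Its reads include the miR156 sequence shared by 6 loci, so this value is not a measure of MIR156a alone. MIR156e, another of these loci, went down, from 99.8 ± 0.0585% to 99.4 ± 0.130% and 99.6 ± 0.0675% (SD, n = 3). Single precursors moved both ways: 21 were separated upward and 13 downward in cyp71-2, and 20 and 21 in cyp71-3, where chance separates 10% over both directions together. Reads that match several precursors were counted in each, so the 95 are not independent. MIR8167a to MIR8167f, for instance, had identical values, with 2.52% of reads at an annotated end in Col-0. These and other precursors, such as MIR400 with 0.596% in Col-0, gave few reads at mature ends. The median over the 95 therefore does not measure miRNA processing alone. Over the 44 precursors with at least 100 RPM the medians were 97.0%, 96.9% and 96.9%, and the differences from Col-0, downward in both mutants, were within the spread (exact permutation p = 0.4 in each).

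Trans-acting siRNAs (tasiRNAs) are made from TAS transcripts cut by a miRNA. Of 8 tested TAS loci, 4 were called lower and 1 higher in each mutant on the deposited scaling. Summed over TAS loci, tasiRNAs were lower in both mutants, at 18038 ± 3152 RPM in Col-0, 9432 ± 1393 RPM in cyp71-2 and 9154 ± 939 RPM in cyp71-3 (SD, n = 3), with no overlap (two-sided exact permutation test, p = 0.1). TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277, TAIR10.1), cut by miR173, fell from 8718 ± 1699 to 3921 ± 608 and 3664 ± 370 RPM (SD, n = 3). TAS3 (AT3G17185, chromosome 3, 5861491 to 5862437), cut by miR390 and a source of siRNAs against auxin response factors, fell from 557 ± 90.1 to 248 ± 35.4 and 330 ± 41.5 RPM (SD, n = 3). TAS4 (AT3G25795, chromosome 3, 9417551 to 9418705), cut by miR828, rose from 37.9 ± 5.01 to 99.2 ± 21.5 and 81.2 ± 15.9 RPM (SD, n = 3).

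In a limma fit of 244 loci, TAS1A fell by 0.90 and 0.95, TAS1B by 0.97 and 1.40, TAS1C by 1.14 and 1.24, and TAS3 by 1.16 and 0.75 on the log2 scale in cyp71-2 and cyp71-3, while TAS4 rose by 1.35 and 1.07. The largest Benjamini-Hochberg adjusted p of these limma values was 0.000151, for TAS3 in cyp71-3. TAS2 (AT2G39681, chromosome 2, 16539384 to 16540417), the neighbour of TAS1C and also cut by miR173, stood at 2242 ± 373, 1717 ± 278 and 1795 ± 185 RPM (SD, n = 3) and did not pass (limma, Benjamini-Hochberg adjusted p = 0.0505 and 0.113). TAS3b and TASIR-ARF, scarcer loci of the TAS3 family, did not pass either, with log2 changes of 0.13 and 0.23 in cyp71-2 and 0.09 and -0.17 in cyp71-3, and without Col-0 replicate 3 the direction turned for TASIR-ARF in cyp71-2 and TAS3b in cyp71-3. TAS2 passed without Col-0 replicate 3 in both mutants and without cyp71-2 replicate 1 in cyp71-2. With median-of-ratios size factors the summed fall was 0.53 and 0.48 on the log2 scale, where it fell by 0.93 and 0.97 as deposited. Single TAS loci were tested on the deposited scaling only. The 21-nt share of TAS reads was 78.2 ± 0.383%, 72.0 ± 0.335% and 71.7 ± 0.329% (SD, n = 3).

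**Figure D4:**
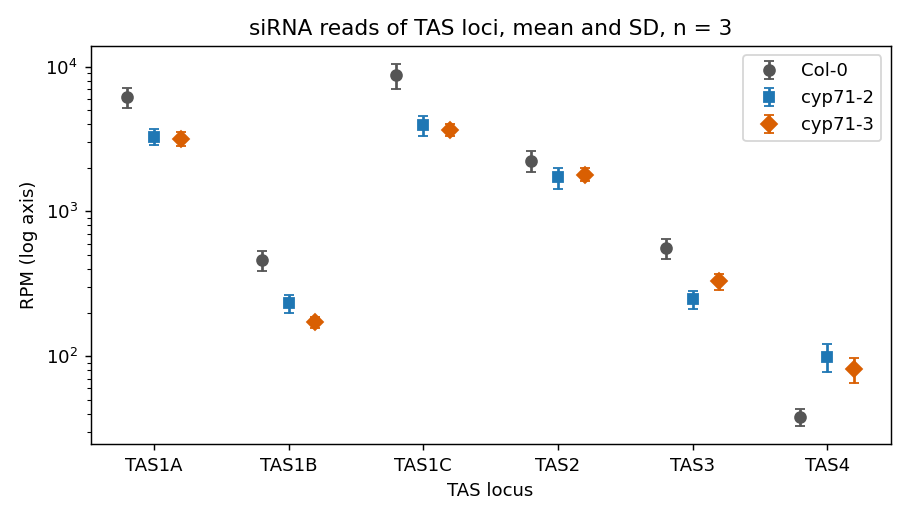
siRNA reads of 6 TAS loci, in RPM on a log axis, for Col-0, cyp71-2 and cyp71-3. Symbols are means and whiskers SDs of 3 libraries; TAS1A, TAS1B, TAS1C and TAS3 lie lower and TAS4 higher in both mutants.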

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

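The tests of explanations and the counts over other splits in this part were all written down after the results they bear on had been seen, as were the 16-nt and pseudogene measurements, so each reading is a hypothesis.

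Between the 2 mutants, limma called miR393b-3p, with a log2 difference (cyp71-3 minus cyp71-2) of -1.15. The difference was -1.11 for miR843. It was -0.74 for miR399b,miR399c-3p and -0.71 for miR822-5p. For miR395b/c/f it was 0.72.

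siRNAs of loci annotated as pseudogenes lay outside the planned comparisons and were higher in both mutants: of 3269 tested, 2410 were higher and 119 lower in cyp71-2, and 2599 higher and 91 lower in cyp71-3 (limma, Benjamini-Hochberg adjusted p under 0.05). Transposons annotated as pseudogenes were not told apart from other loci of this class. A smaller share of rRNA reads would raise all other nuclear siRNAs alike, but 24-nt reads of pseudogenes per 24-nt read of other nuclear DNA were at least 0.485 in every mutant library and at most 0.344 in Col-0, which argues against it as the whole cause. A segment of another strain carried with the mutations would sit in part of the genome, but at least 69.9% of tested pseudogenes were called higher on each of the 5 chromosomes in both mutants. The 10 splits of 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 2529 calls in cyp71-2 and 2690 in cyp71-3, and the highest other gave 0 in each. A genotype effect on silencing of these loci may be the source, but neither this nor any further explanation was tested.

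Reads of 16 nt that begin TCCGCTGTAGCAC, a sequence with 22 genome sites of which 1 lies in an annotated gene, were 6.82-fold higher in cyp71-2 and 4.22-fold higher in cyp71-3 than in Col-0, a signal outside the miRNA measurements. Nuclear tRNA fragments of 16 nt took 2.77% of reads in cyp71-2 and 1.80% in cyp71-3, against 1.18% in Col-0. Degraded RNA or a lower gel slice would raise 16-nt reads of 45S rRNA as much. Their share of 45S rRNA reads rose at most 1.27-fold between any mutant and any Col-0 library. The repeated sequences rose at least 3.04-fold, but as a level in RPM, and a share set against a level cannot exclude these causes. Reads of all lengths that begin with the repeated sequence were 6.42-fold and 4.17-fold higher in cyp71-2 and cyp71-3, so the rise was not limited to 16 nt. The 16-nt share of tRNA reads lay above Col-0 in every mutant library, but the smallest ratio was 1.01, within that of rRNA, and the ratio of means was 1.51 in cyp71-2 and 1.14 in cyp71-3 against 1.19 and 1.21 for rRNA, so for tRNA ends degradation or the gel slice cannot be told apart from a change in tRNA fragments. No other explanation was tested for either.

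TAS1 siRNAs were lower in both mutants, and their trigger miR173-5p was called lower in cyp71-2 only, with libraries that overlapped Col-0 and a call that was lost with median-of-ratios size factors. Less miR173 alone would lower TAS2 as much as TAS1C, but log2 of TAS1C reads per TAS2 read changed by -0.76 in cyp71-2, the smaller of the falls in the 2 mutants, with no overlap of libraries. A change in the total used for scaling could end the fall under some scaling. The smallest fall of summed TAS reads over 3 scalings was -0.48 (log2), so none of these ended it. None of the 3 is a known reference, so a change in the total is not excluded. A genotype effect on a step after cleavage may contribute but was not tested, nor were other differences that run with genotype.

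For miRNAs the 10 splits are again too few for a share under 0.05. In cyp71-2 the real split called 68 and the highest other 0, and in cyp71-3 they called 59 and 0, so 1 split, the real one, gave as many. Between the mutants the real split called 11 and the highest other 1. For lists, camera called 1 in the real split of cyp71-2 and 3 in the highest other, and 1 and 2 for cyp71-3, with 4 of the 10 splits calling as many as the real one in each.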

How the results depend on the processing

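Alternatives chosen after seeing the data were the scalings to reads of 17 to 26 nt and to reads outside rRNA, tRNA, snRNA and snoRNA, the other scalings of summed TAS reads, the block for TAS loci, and those for the agreement of the 2 mutants. Of 2190 values of named miRNAs and loci under alternatives, 1958 kept their direction and side of the threshold, 103 no longer passed, 63 newly passed in the same direction and 66 reversed. Some of the reversed values passed in their new direction. No miRNA called in both the main fit and an alternative changed direction. Except where said below by construction, the cause was not tested.

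With a mean of at least 10 RPM, fewer miRNAs were tested (58), and by construction counts fell to 28 lower and 11 higher in cyp71-2, 25 lower in cyp71-3 and 4 between mutants. Counting isomiRs tested more (180) and gave 28 higher in cyp71-2, and 78 lower and 17 higher in cyp71-3. Median-of-ratios size factors, which centre the median miRNA change by construction, gave 33 higher in cyp71-2, 30 higher in cyp71-3 and 21 between mutants. Total miRNA then changed by 0.28 and 0.37 (log2). Scaling to 24-nt reads gave 18 between mutants, and scaling to reads outside rRNA, tRNA, snRNA and snoRNA gave 83 lower in cyp71-3. edgeR called 30 lower and 34 higher in cyp71-2 and 34 higher in cyp71-3. DESeq2 called 33 lower and 29 higher in cyp71-2, 31 lower and 27 higher in cyp71-3, and 19 between mutants. With an estimated correlation camera called 0 lists in each mutant, where fry called 3 and 4 and the unadjusted p of the nutrient-responsive list was 0.141 and 0.137.

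Under median-of-ratios, edgeR and DESeq2 in that order, log2 changes reversed to 0.26, 0.31 and 0.26 for miR161.1, 0.31, 0.37 and 0.31 for miR166 (miR166c/d/f/g,miR166a/b/e-3p), 0.12, 0.17 and 0.11 for miR158a-3p, 0.29, 0.36 and 0.30 for miR168a/b-5p, and 0.065, 0.15 and 0.085 for miR827 in cyp71-2. In cyp71-3 they reversed to 0.47, 0.49 and 0.47 for miR161.1, 0.38, 0.40 and 0.38 for miR393b-3p, 0.36, 0.38 and 0.36 for miR157a/b/c-5p, and 0.36, 0.39 and 0.37 for miR171a-3p. They also reversed there to 0.23, 0.25 and 0.23 for miR158a-3p, 0.14, 0.16 and 0.14 for miR166, 0.12, 0.14 and 0.12 for miR172 (miR172a,miR172b-3p), 0.019, 0.036 and 0.013 for miR173-5p, and under edgeR to 0.0028 for miR5026. In cyp71-2, miR161.1 and miR166 passed as higher under each of these methods. So did miR161.1, miR393b-3p, miR157a/b/c-5p and miR171a-3p in cyp71-3. None of the other reversals under these methods passed. All of these methods scale on the miRNAs themselves, so they are not independent of one another. Scaling to 24-nt reads reversed miR168a/b-5p to -0.12 and miR319a/b to -0.073 in cyp71-3. Scaling to reads outside rRNA, tRNA, snRNA and snoRNA reversed miR319a/b and miR393a/b-5p to -0.043 and -0.041 in cyp71-2, and miR168a/b-5p, miR319a/b and miR390a/b-5p to -0.24, -0.19 and -0.060 in cyp71-3. Also in cyp71-3, isomiRs gave 0.020 for miR157a/b/c-5p and -0.0081 for miR168a/b-5p, and scaling to reads of 17 to 26 nt gave 0.031 for miR161.1. The 21-nt share in cyp71-2 changed by 0.12 percentage points with each distinct sequence counted once. The 24-nt share in cyp71-2 changed by -0.57 points without rRNA, tRNA, snRNA and snoRNA reads. Precision over precursors with at least 100 RPM changed by -0.086 points in cyp71-2 and -0.071 in cyp71-3. Pearson's r between the mutants was 0.874 and 0.936 with pseudocounts of 0.1 and 10 RPM, 0.946 with a mean of at least 10 RPM, 0.866 with edgeR and 0.866 with DESeq2.

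Leaving out 1 library at a time gave 40 to 54 lower and 12 to 18 higher in cyp71-2, 40 to 64 lower and 9 to 10 higher in cyp71-3, 7 to 13 between mutants (7 without Col-0 replicate 2, cyp71-3 replicate 2 or cyp71-3 replicate 3), and r of 0.879 to 0.910. The 24-nt difference ranged from -0.21 (without Col-0 replicate 3) to 1.64 points in cyp71-2 and from 1.62 to 3.47 in cyp71-3, the 21-nt difference from -1.92 to -1.56 and from -2.03 to -1.84. Summed TAS reads changed by -1.08 to -0.81 and -1.12 to -0.88 (log2), total miRNA by -0.21 to -0.01 and -0.19 to -0.04, and precision by 4.56 to 5.17 and 5.24 to 5.84 points. Log2 changes that reversed without some library ranged in cyp71-2 from -0.24 to 0.036 for miR166c/d/f/g,miR166a/b/e-3p, -0.21 to 0.080 for miR168a/b-5p, -0.026 to 0.34 for miR393a/b-5p, -0.40 to 0.076 for miR827 and -0.025 to 0.38 for TASIR-ARF siRNAs. In cyp71-3 they ranged from -0.33 to 0.033 for miR157a/b/c-5p, -0.070 to 0.076 for miR161.1, -0.069 to 0.21 for miR168a/b-5p, -0.28 to 0.011 for miR171a-3p, -0.065 to 0.25 for miR319a/b, -0.18 to 0.00072 for miR393b-3p and -0.0016 to 0.19 for TAS3b siRNAs.

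The replicate numbers did not pair the libraries: of 9 same-number pairs 2 had a correlation of deviations over 0.1 (range -0.20 to 0.16), and 0 libraries correlated best with their own number. The replicate block gave 51 lower and 17 higher in cyp71-2, 54 and 11 in cyp71-3, 11 between mutants, 1 list in each mutant and an r of 0.905; total miRNA changed by -0.12 and -0.11 (exact sign-flip p = 0.5 and 0.75, smallest possible 0.25). TAS2 passed in cyp71-2 with the block (limma, Benjamini-Hochberg adjusted p = 0.0304).

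Depth limited scarce miRNAs most: in the shallowest library, of 5538323 reads, 1 RPM was 5.54 reads and a count of 0 allowed up to 0.542 RPM.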

Other observations

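The measurements in this part were chosen after the data were seen. Fragments of other RNAs also differed between genotypes. Nuclear tRNA fragments took 3.98 ± 0.128% of reads in Col-0, 6.19 ± 0.207% in cyp71-2 and 5.33 ± 0.204% in cyp71-3 (SD, n = 3), and plastid tRNA fragments 1.35 ± 0.00854%, 1.97 ± 0.0339% and 1.98 ± 0.0985% (SD, n = 3). Fragments of 16 nt from the 5′ end of tRNAs of all amino acids stood at 11142 ± 1431 RPM (SD, n = 3) in Col-0, and at 2.41-fold and 1.54-fold of it in cyp71-2 and cyp71-3. Among these, tRNA-Gly stood at 1.48-fold and 1.88-fold and tRNA-Glu at 1.73-fold and 1.56-fold. The scarce tRNA-Asn, with the largest ratios given here, stood at 151 ± 51.7, 1111 ± 165 and 823 ± 133 RPM (SD, n = 3), and tRNA-Ala stood at 5569 ± 1319, 17144 ± 3673 and 7015 ± 807 RPM (SD, n = 3), where cyp71-3 overlapped Col-0 (two-sided exact permutation test, p = 0.2). Plastid rRNA fragments took 10.3 ± 1.55%, 7.32 ± 1.03% and 7.19 ± 0.455% of reads, and mitochondrial reads 0.745 ± 0.0301%, 0.979 ± 0.0414% and 1.05 ± 0.0504% (SD, n = 3). Except for tRNA-Ala in cyp71-3, each mutant was separated from Col-0 in these values (two-sided exact permutation test, p = 0.1, the smallest possible). Fragments of 16 nt from the 5′ end of tRNA-Asp, also measured, stood at 59.8 ± 33.2, 155 ± 28.2 and 69.1 ± 3.65 RPM (SD, n = 3). There cyp71-3 overlapped Col-0 as well (exact permutation p = 0.4).

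An 18-nt rRNA fragment, GCGGACTGCTCGAGCTGC, was at 16182 ± 2583, 26403 ± 970 and 39512 ± 443 RPM (SD, n = 3). Among siRNAs of pseudogenes, 2326 loci were higher in both mutants and 72 lower in both, and the log2 changes correlated across loci with an r of 0.933, where loci are not independent and the Col-0 libraries are shared. Simulated unchanged groups against the same controls gave an r of 0.499 and 0 shared calls, independent lists would share 1916 and 3.31 loci, and the covariance was 0.366 against 0.0163 simulated, a difference of 0.349. The 3 controls cannot be split, so part of the excess may come from them. Scaled to 24-nt reads, 2400 were higher and 159 lower in cyp71-2, and 2367 and 134 in cyp71-3 (limma, Benjamini-Hochberg). AT2G10180 (chromosome 2, 3866573 to 3872675, TAIR10.1) went from 4.57 ± 1.15 to 43.8 ± 5.69 and 31.1 ± 3.23 RPM (SD, n = 3), and was picked for its large change.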
